A study of Homo sapiens with 12 samples.

How the data were processed

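HK-2 is an immortalised line of human renal proximal tubular epithelial cells. Per the labels, the cells were grown in DMEM and Ham's F12 with 5 mM glucose, epidermal growth factor, hydrocortisone, insulin, transferrin and selenite, seeded the day before treatment and treated close to confluence with the compound named CdCl or with the control vehicle for 12 h or 48 h. The dose is not given in the sources used here. Each of the 4 groups holds 3 biological replicates, 1 array each, for 12 arrays. Total RNA was isolated on RNeasy columns, and biotin-labelled cRNA was hybridised to Affymetrix arrays carrying 54675 probe sets.

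The deposited values are log2 signals per probe set, which per the labels the authors made with GCRMA, a method that corrects background by probe sequence, normalises the probes between arrays and summarises each probe set. Its version is not given in the sources used here. Array medians lay between 2.97 and 3.04 and maxima between 15.65 and 15.79 on the log2 scale, and no value was missing. The deposited values were used as they are. Detection calls and scanner images were not used here, so signal over background limits what can be seen of weakly expressed genes, and the number of arrays limits the precision.

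Gene symbols came from the probe annotation given for the platform. Of the probe sets, 41091 carried exactly 1 symbol, 1801 carried several and 11777, control probe sets included, carried none. Affymetrix control probe sets, 62 in number, were left out of the gene tests and used only to describe the arrays. Each of 19775 genes was represented by its probe set with the highest mean over the 12 arrays, and 10523 genes had more than 1. A gene was tested if its value exceeded 4 on at least 3 of the 12 arrays, which left 10683 genes. No genome coordinates were used.

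One limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes with a constant prior) of the 4 group means over the 12 arrays gave 4 two-sided comparisons. These were CdCl against control at 12 h, CdCl against control at 48 h, the difference between these effects (48 h minus 12 h, the interaction) and control at 48 h against control at 12 h. P values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Changes are log2 differences, given with the standard error (SE) of the fit as value ± SE, and group levels are means ± standard deviation (SD) of 3 arrays. Where all 3 arrays of a group lay under 4, the fold change is a lower bound, computed with that group set to 4 and written "at least". No adjustment was made for pairing by replicate number, a choice fixed beforehand. A later check saw no pairing by number, although 3 arrays per group cannot exclude it. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1, so gene calls rest on the spread pooled over genes.

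The 30 gene lists cover metal, heat, oxidative and endoplasmic reticulum stress, growth, metabolism, tubule identity and other renal cell types, and 27 of them had at least 5 tested members. Each was tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list moves on balance without comparing it with other genes, were run beside it. List counts are also given adjusted over the list alone. Some genes stand in more than 1 list: ATF3 in the ATF4 and immediate early lists, SQSTM1 in the NRF2 and autophagy lists, GCLM in the NRF2 and glutathione lists, GCLC, GSR and GPX2 in the same pair, ABCC2 in the NRF2 and proximal tubule lists, GGT1 in the proximal tubule and glutathione lists, BAX, BBC3, FAS and TNFRSF10B in the p53 and apoptosis lists, and BIRC3 in the NF-kB and apoptosis lists.

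Groups, the 4 comparisons, tests, filter, gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The comparison of CdCl cells at 48 h with CdCl cells at 12 h, from the same group means, was added after the data were seen. Named genes are the 10 largest rises and the 10 largest falls at each time among genes past the threshold whose 3 CdCl arrays all lay beyond the 3 controls, which chance gives in 10% of unchanged genes in either direction. For the interaction and the control comparison they are the 5 largest in each direction, for the interaction without that condition. The rule adds up to 4 members of each list with the largest absolute change at each time, and 16 index genes. Of the list members the text gives the first 2 or 3 in rule order, and none for lists summarised by counts, a number chosen after the values were seen, as were the 48 h value of GJA1 and the 12 h value of VCAM1. Of the index genes, HSPA1A had no probe set with 1 symbol and LRP2 lay under the filter.

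The pipeline was tested on simulated data with the means and residual SD of the 10683 genes. With 200 genes changed, the 12 h comparison recovered 71.6% of changes of 0.5, 97.0% of changes of 1 and 100% of changes of 2 log2 units, and 4.81% of its calls were false. The interaction recovered 34.3%, 80.6% and 98.5%, with 7.78% of its calls false. A list of 25 genes moved by 0.5 passed camera, and 0 of 27 unchanged lists did. Simulated genes varied independently of each other, while the real metallothionein list had an estimated correlation of 0.24. False list calls among correlated genes were thus not tested. Far fewer genes changed in the simulation than were called in the real data, 56.4% at 12 h, and no simulated array carried a shift shared by its genes. The recovered and false shares therefore hold for the simulated setting only.

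The alternatives were no filter and a filter at 6, a floor at 4, quantile normalization, centring each array on its median, the mean of all probe sets of a gene, the second highest probe set, every probe set on its own, eBayes with trend and robust, only the groups compared, array weights, a replicate block, stricter thresholds and leaving out each array in turn. Probe sets with no symbol or several are counted in the closing section, with no names. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.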

Results

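Gene expression was measured on 12 Affymetrix arrays from HK-2 cells, an immortalised human renal proximal tubular epithelial line, exposed to CdCl or to the control vehicle for 12 h or 48 h, with 3 biological replicates in each of 4 groups. The series belongs to a study of 9 compounds that looked for expression signatures of kidney toxicity. Over all probe sets but the Affymetrix controls, replicates of a group correlated at 0.9965 to 0.9982. Arrays of different groups correlated at 0.9731 to 0.989. The first principal component carried 51.8% of the variance and the second 31.9%, and the 4 groups lay apart on them.

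**Figure D1:**
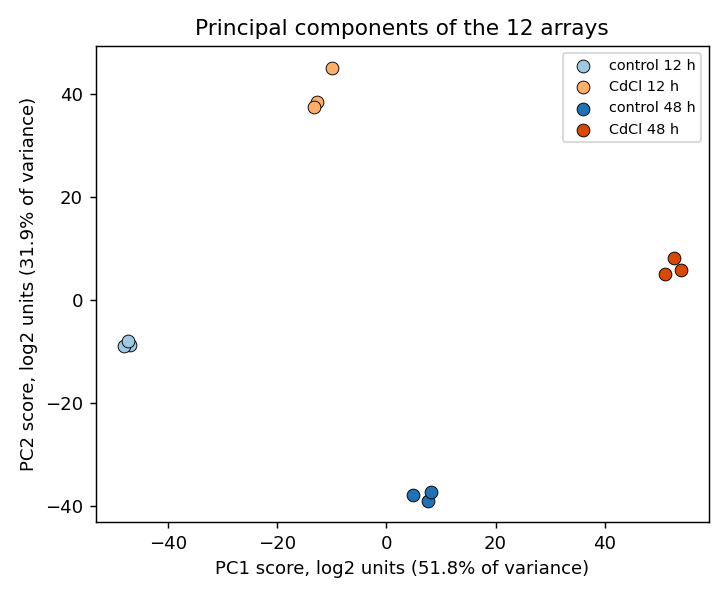
Scores of the 12 arrays on the first (x) and second (y) principal components of the tested genes, in log2 units, 1 point per array and 1 colour per group of 3. The control 12 h arrays lie at -48.13 to -46.9 and the CdCl 48 h arrays at 51.02 to 53.89 on the first component, with the CdCl 12 h and control 48 h arrays between them and apart on the second.

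Poly-A spike-ins, control RNAs added before labelling, averaged 6.53 ± 0.13 (SD, n = 3) in control and 7.00 ± 0.04 in CdCl arrays at 12 h, a difference of 0.47 with all 3 CdCl arrays above all 3 controls (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allow). At 48 h they averaged 6.14 ± 0.10 in control and 6.31 ± 0.49 in CdCl arrays, and all 3 control 48 h arrays lay below all 3 control 12 h arrays (-0.39, exact permutation p = 0.1, two-sided). Hybridisation controls averaged 10.62 in both groups at 12 h, 10.52 in control and 10.32 in CdCl arrays at 48 h. The difference between the 3' and 5' actin probe sets, a sign of RNA integrity, was 1.90, 1.74, 1.495 and 1.63 in control 12 h, CdCl 12 h, control 48 h and CdCl 48 h arrays, with all 3 control 48 h arrays below all 3 at 12 h (-0.41, exact permutation p = 0.1, two-sided). The same measure for GAPDH was lower in all 3 CdCl than in all 3 control arrays at 12 h (-0.15) and in all 3 control arrays at 48 h than at 12 h (-0.13), each with an exact permutation p = 0.1.

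The comparison at 12 h asked which transcripts CdCl changed early. Genes for metal binding, oxidative stress, heat shock and protein folding in the endoplasmic reticulum rose, and genes for DNA replication and mitosis fell. Among the genes tested the largest change was in HSPA6, an inducible heat shock protein of the HSP70 family, whose signal went from 2.5 ± 0.04 in control to 10.99 ± 0.11 in CdCl cells (SD, n = 3), at least 127-fold higher. HMOX1, which encodes the haem-degrading enzyme heme oxygenase 1, was 75.7-fold higher, with all 3 CdCl arrays above all 3 controls (log2 change 6.24 ± 0.08, adjusted p = 5.9e-13). Of 10683 genes tested with limma, 1783 were higher and 4246 lower with CdCl, and 473 and 433 of these by at least 2-fold. The median change of all tested genes was -0.16 on the log2 scale, and list medians at 12 h are given relative to it.

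Of the 8 metallothionein genes tested, which encode small metal-binding proteins, 7 rose and 0 fell, also when adjusted over the list alone (7 and 0), with a median 1.97 above that of all genes (camera adjusted p = 5.0e-10). MT1M rose 28.2-fold (4.82 ± 0.14), MT1G by 2.98 ± 0.10 (1.42 on its second probe set) and MT1F by 2.19 ± 0.06 on the log2 scale. MT1X rose 4.09-fold, to 14.90, and MT2A 2.16-fold, to 15.31, near the top of the array scale. Except for MT1M, the probe sets of these genes can cross-hybridise between family members. Among 22 zinc and metal transporters, 6 rose, 3 fell and 13 did not pass, the same numbers when adjusted over the list alone (camera adjusted p = 0.075), and 8 rose and 2 fell after centring each array on its median. The vesicular zinc transporter SLC30A2 rose by 1.92 ± 0.10, the zinc exporter SLC30A1 by 1.78 ± 0.06 and the zinc and iron importer SLC39A14 by 1.25 ± 0.09 (3.36 on its second probe set).

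Of 25 heat shock proteins and co-chaperones, 23 rose, 1 fell and 1 did not pass, with 23 and 1 adjusted over the list alone (median 1.34 above all genes, camera adjusted p = 1.2e-18). Beside HSPA6, the co-chaperone genes BAG3 and DNAJB1 rose 9.37-fold and 6.92-fold. Of 29 tested genes in the list of targets of NRF2, the transcription factor of the oxidative stress response, 25 rose and 2 fell, with 25 and 2 adjusted over the list alone (median 1.41 above all genes, adjusted p = 1.2e-17). The list as fixed also holds NFE2L2, the gene of NRF2 itself, and TXNIP. The cystine transporter gene SLC7A11 rose 21.3-fold (4.41 ± 0.10), and AKR1B10, an aldo-keto reductase, was at least 8.38-fold higher. GCLM, a subunit of the first enzyme of glutathione synthesis, rose 7.79-fold and the sulfiredoxin gene SRXN1 4.44-fold.

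Of 22 endoplasmic reticulum chaperone and unfolded protein response genes, 19 rose and 1 fell, with 19 and 1 adjusted over the list alone (median 1.38 above all genes, adjusted p = 6.0e-15). DNAJC3 rose by 2.55 ± 0.16, DNAJB9 by 2.45 ± 0.08 and SDF2L1 by 2.23 ± 0.13, all of them luminal chaperones or co-chaperones, and the chaperone HSPA5 rose by 1.63 ± 0.08, to 14.77 (a change of 3.52 on its second probe set). Of 30 genes of the ATF4 amino acid and stress response, 19 rose and 6 fell, with 19 and 6 adjusted over the list alone and 21 and 2 after centring (median 0.84 above all genes, adjusted p = 1.9e-09). The transcription factor gene ATF3 rose 126-fold, DDIT3, which encodes the stress factor CHOP, 16.2-fold and PPP1R15A, a phosphatase subunit that acts on eIF2alpha, 12.4-fold. Of 24 autophagy and lysosome genes, 10 rose and 3 fell, with 10 and 3 adjusted over the list alone (adjusted p = 0.0012). These included MAP1LC3B (1.79 ± 0.08), the cathepsin gene CTSL (1.46 ± 0.06) and GABARAPL1 (1.29 ± 0.17).

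Of 17 NF-kB and inflammatory genes, 11 rose and 2 fell, with 11 and 2 adjusted over the list alone (median 0.85 above all genes, adjusted p = 3.9e-06). The cytokine gene IL11 was at least 9.85-fold higher, the NF-kB inhibitor TNFAIP3 rose 8.51-fold and IL6 rose 6.41-fold. Of 19 immediate early genes, which respond within minutes to signals, 12 rose and 0 fell, with 13 and 0 adjusted over the list alone and 16 and 0 after centring (median 0.54 above all genes, adjusted p = 2.7e-08). They include ATF3, FOSL1 (4.25-fold) and IER5 (4.17-fold). Of 26 hypoxia and glycolysis genes, 20 rose and 0 fell, also when adjusted over the list alone (20 and 0), with a median 0.76 above all genes (adjusted p = 8.2e-14). The vasoactive peptide gene ADM rose 9.41-fold, the glucose transporter SLC2A1 5.42-fold and the hexokinase gene HK2 4.97-fold, although the second probe set of HK2 gave -0.52 and no call.

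Of 28 DNA replication and G1/S genes, 27 fell and 1 rose, also when adjusted over the list alone (27 and 1), with a median -0.82 from that of all genes (adjusted p = 7.1e-09). The cyclin gene CCNE2 changed by -1.55 ± 0.13, GINS1 by -1.37 ± 0.07, E2F2 by -1.35 ± 0.10 and the replicative helicase gene MCM5 by -1.11 ± 0.11. Of 28 mitosis and G2/M genes, 27 fell and 0 rose, also when adjusted over the list alone (27 and 0), with a median -0.82 from all genes (adjusted p = 2.6e-09). The proliferation marker MKI67 changed by -1.43 ± 0.15, HMMR by -1.32 ± 0.12, CENPF by -1.22 ± 0.10 and the cyclin gene CCNB1 by -0.77 ± 0.06. Of 20 p53 targets, 6 rose and 10 fell, also when adjusted over the list alone (6 and 10), with 7 and 8 after centring, and the list did not pass (adjusted p = 0.63). The cell cycle inhibitor CDKN1A rose 2.01-fold, GADD45A 8.01-fold and GDF15 2.39-fold, while the DNA repair gene DDB2 was 4.37-fold lower.

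Of 14 tested genes of proximal tubule function, 4 rose and 5 fell, also when adjusted over the list alone (4 and 5; list adjusted p = 0.60), and after centring 5 rose and 5 fell. The efflux pump gene ABCC2 was at least 2.88-fold higher, the kidney cadherin CDH16 changed by -1.12 ± 0.17 and GATM, an enzyme of creatine synthesis, by -0.87 ± 0.12. Of 22 tubular injury markers, 8 rose and 5 fell, also when adjusted over the list alone (8 and 5; list adjusted p = 0.10), and after centring 10 rose and 2 fell. CD44 rose by 0.96 ± 0.09, CCN2 by 0.71 ± 0.11 and HAVCR1, which encodes kidney injury molecule 1, by 0.59 ± 0.12. Extracellular matrix and mesenchymal genes rose in 10 and fell in 7 of 21 members, with 10 and 8 adjusted over the list alone. Their camera adjusted p was 0.048, and adjusted p = 0.21 with an estimated correlation. The transcription factor gene SNAI2 was at least 3.10-fold higher, and ZEB2 and the collagenase MMP1 rose 5.05-fold and 4.89-fold. Of 19 cholesterol synthesis genes, 4 rose and 7 fell, also when adjusted over the list alone (4 and 7; list adjusted p = 0.63), and after centring 4 rose and 3 fell. STARD4 rose by 1.28 ± 0.08, HSD17B7 by 1.07 ± 0.07 and HMGCS1, the synthase that precedes HMG-CoA reductase, by 0.49 ± 0.07 (2.16 on its second probe set). Of 31 respiratory chain genes 19 fell and 0 rose, also when adjusted over the list alone (19 and 0; adjusted p = 0.040, and adjusted p = 0.44 with an estimated correlation), and 4 fell after centring each array on its median.

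Other genes among the 10 largest rises were ZFAND2A, a zinc finger protein of the arsenite response (125-fold), and ANKRD1, CLIP4, DLX2 and LINC00304, which were higher by at least 44.0, 23.2, 12.3 and 6.84-fold. The second probe set of CLIP4 gave a log2 change of 2.37. The 10 largest falls were smaller. CCDC146 changed by -2.61 ± 0.18, the cell cycle factor E2F8 by -2.35 ± 0.13, the helicase BLM by -2.31 ± 0.25, the cadherin FAT4 by -2.26 ± 0.27, the separase gene ESPL1 by -2.24 ± 0.14, FAM111A-DT by -2.23 ± 0.10, the linker histone H1-10 by -2.14 ± 0.14 and ORC1, a subunit of the origin recognition complex, by -2.07 ± 0.19. OLFML2A was at least 2.19-fold lower, and DDB2 completes the group.

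Lower genes made up 70.4% of the 12 h calls as deposited, 58.2% after quantile normalization and 52.1% after centring each array on its median, while the spike-ins were higher in all 3 CdCl arrays. Of the 13 lists past the threshold, 11 also passed with an estimated correlation, while the extracellular matrix call ended without control 12 h replicate 1 (median -0.04), CdCl 12 h replicate 1 or 3, control 48 h replicate 2 or CdCl 48 h replicate 1 or 2 (adjusted p = 0.051 to 0.089), and the respiratory chain call ended without any 12 h array but control replicate 2 (adjusted p = 0.052 to 0.061).

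**Figure D2:**
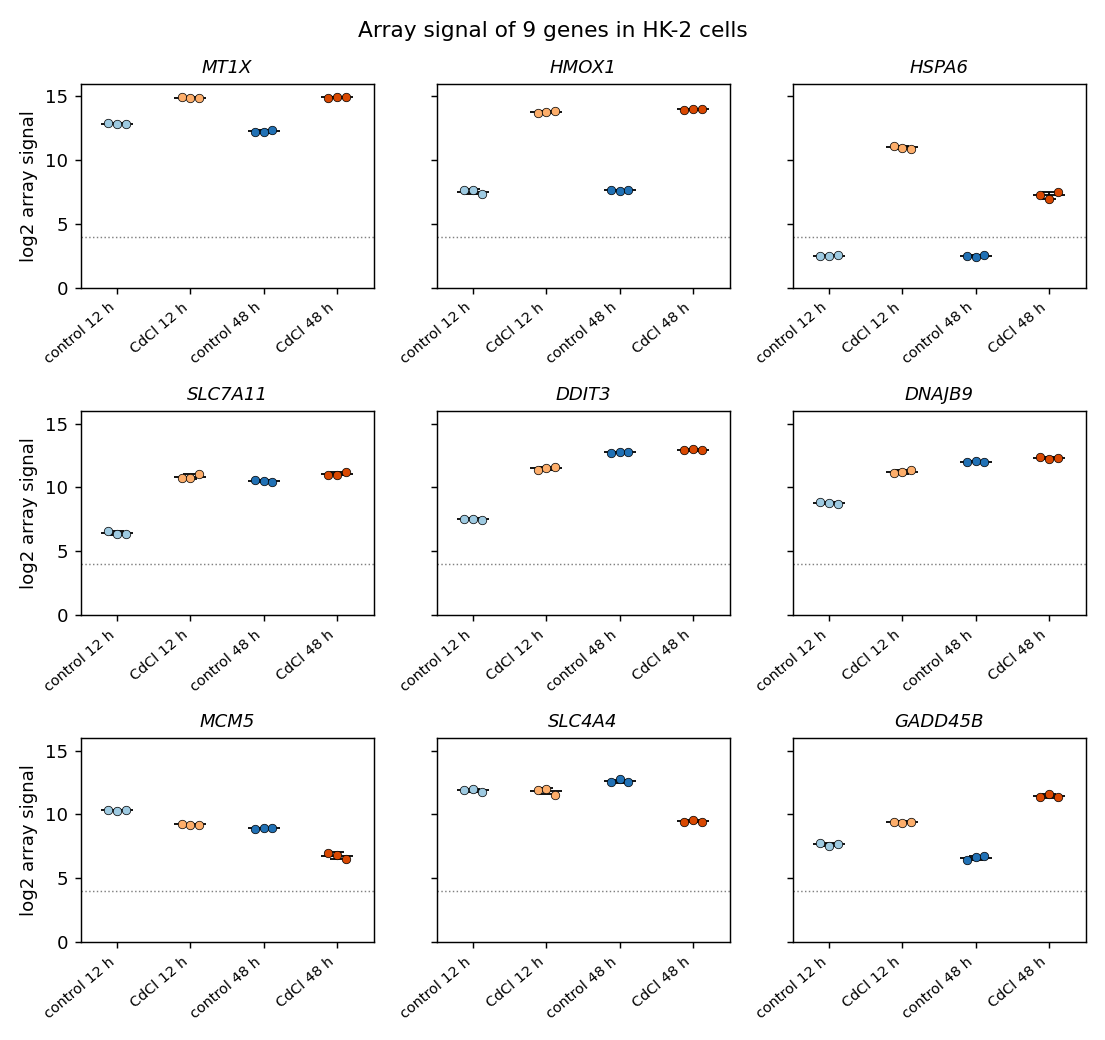
Log2 array signal (y) of 9 named genes in the 4 groups (x), with 1 point per array, the mean as a bar and the SD as the error (n = 3), and a dotted line at 4. HMOX1 and MT1X are high in CdCl cells at both times, DDIT3 and DNAJB9 are already high in control cells at 48 h, and SLC4A4 falls and GADD45B peaks in CdCl cells at 48 h.

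At 48 h the comparison asked which transcripts stayed changed or changed late. Metallothioneins and NRF2 targets were again higher with CdCl, as were heat shock genes (adjusted p = 0.051 with an estimated correlation), replication and mitosis genes were lower, and SLC6A13 and CLDN2, of tubular transport, were among the largest falls. MT1M went from 7.64 ± 0.35 in control to 14.14 ± 0.12 in CdCl cells (SD, n = 3), 90.1-fold higher, and HMOX1 was 81.1-fold higher. Of the genes tested, 2835 were higher and 2995 lower, 515 and 540 of them by at least 2-fold, with a median change of -0.02 over all tested genes. Genes higher at both times numbered 1217, where 473 would be so by independent chance, and 2035 were lower at both, against 1190. Changes at both times correlated across genes (Pearson's r = 0.63, Spearman's rho = 0.55), but genes are not independent replicates and each time has its own controls.

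Of 8 metallothioneins, 7 rose and 0 fell, also when adjusted over the list alone (7 and 0; median 2.54, camera adjusted p = 2.5e-08). MT1G rose by 3.81 ± 0.10 (1.20 on its second probe set), MT1X by 2.68 ± 0.07 and MT2A by 1.97 ± 0.06, to 15.35. Of 22 zinc and metal transporters, 13 rose and 2 fell, also when adjusted over the list alone (13 and 2; adjusted p = 0.042, and adjusted p = 0.10 with an estimated correlation). SLC30A2 rose 5.46-fold and SLC30A1 4.12-fold, and the iron exporter SLC40A1 changed by -1.98 ± 0.18. Of 25 heat shock genes, 21 rose and 1 fell, also when adjusted over the list alone (21 and 1; median 0.76, adjusted p = 2.5e-08, and adjusted p = 0.051 with an estimated correlation). HSPA6 was at least 9.43-fold higher, BAG3 rose 3.88-fold, HSPH1 3.73-fold and DNAJB1 3.06-fold.

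Of 29 NRF2 targets, 24 rose and 3 fell, also when adjusted over the list alone (24 and 3; median 0.93, adjusted p = 2.4e-09). GCLM rose 8.53-fold, the quinone reductase NQO1 6.06-fold and SRXN1 4.26-fold. Of 22 endoplasmic reticulum genes, 16 rose and 2 fell, with 17 and 2 adjusted over the list alone (median 0.42, adjusted p = 5.0e-04, and adjusted p = 0.13 with an estimated correlation). DNAJB11 rose by 0.97 ± 0.07, SDF2L1 by 0.89 ± 0.13 and EDEM1 by 0.86 ± 0.08, while HSPA5 lay at 15.10 in control and 15.26 in CdCl cells (0.16 ± 0.08, adjusted p = 0.12), near the top of the scale, and its second probe set gave a rise of 0.81. Of 30 ATF4 genes, 10 rose and 12 fell, with 11 and 12 adjusted over the list alone, and the list did not pass (adjusted p = 0.85). PPP1R15A rose 7.33-fold and ATF3 3.90-fold, the serine synthesis gene PHGDH changed by -1.77 ± 0.09 and DDIT3 by 0.20 ± 0.08 (adjusted p = 0.042). Of 24 autophagy and lysosome genes 14 rose and 0 fell, also when adjusted over the list alone (14 and 0; median 0.52, adjusted p = 7.2e-05), among them CTSL (1.55 ± 0.06), the cathepsin CTSD (1.20 ± 0.10) and MAP1LC3B (1.17 ± 0.08). Of 28 proteasome subunits 14 rose and 0 fell, also when adjusted over the list alone (14 and 0; adjusted p = 0.0026, and adjusted p = 0.35 with an estimated correlation), with PSMC4 at 0.65 ± 0.07 and PSMD12 at 0.65 ± 0.08.

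Of 28 replication and G1/S genes, 24 fell and 1 rose, also when adjusted over the list alone (24 and 1; median -1.17, adjusted p = 1.7e-10). The licensing factor CDT1 was 6.64-fold lower, MCM5 4.41-fold and CCNE2 4.01-fold. Of 28 mitosis genes, 25 fell and 0 rose, with 26 and 0 adjusted over the list alone (median -0.77, adjusted p = 9.9e-10). CDK1, KIF20A, NUSAP1 and CCNB1 were 3.08, 2.90, 2.73 and 1.71-fold lower. Of 20 p53 targets, 7 rose and 8 fell, also when adjusted over the list alone (7 and 8; list adjusted p = 0.80). GADD45A rose 4.04-fold and CDKN1A 2.11-fold, and SESN1 was 3.88-fold lower.

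Of 14 proximal tubule genes, 5 rose and 7 fell, also when adjusted over the list alone (5 and 7; median -0.29, list adjusted p = 0.15). The basolateral bicarbonate transporter SLC4A4 was 8.91-fold lower (12.61 ± 0.11 in control and 9.46 ± 0.07 in CdCl cells), CDH16 8.47-fold and the cadherin CDH6 4.74-fold. Of 22 injury markers, 4 rose and 6 fell, also when adjusted over the list alone (4 and 6; list adjusted p = 0.94). LCN2, the lipocalin NGAL, rose 5.77-fold and CD44 3.66-fold, while VCAM1 was 4.44-fold and HAVCR1 2.04-fold lower. At 12 h VCAM1 had risen by 0.60 ± 0.19, a call that ended with no filter on low values (adjusted p = 0.054) and without control 12 h replicate 3 or CdCl 12 h replicate 1 or 2 (adjusted p = 0.052 to 0.074). Of 21 extracellular matrix and mesenchymal genes, 12 rose and 6 fell, also when adjusted over the list alone (12 and 6; list adjusted p = 0.082). SNAI2, SNAI1 and MMP1 were at least 8.48, 4.38 and 6.15-fold higher. Of 19 cholesterol synthesis genes, 11 fell and 1 rose, also when adjusted over the list alone (11 and 1; median -0.29, adjusted p = 0.039, and adjusted p = 0.098 with an estimated correlation). INSIG1 changed by -0.93 ± 0.14, SQLE by -0.70 ± 0.09 and HMGCS1 by -0.68 ± 0.07.

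Of 17 NF-kB and inflammatory genes, 7 rose and 3 fell, also when adjusted over the list alone (7 and 3; list adjusted p = 0.29). The chemokine gene CCL2 was at least 4.68-fold lower, and IL6 and IL11 were at least 3.27 and 1.27-fold higher, the IL11 call ending when values were floored at 4. Of 19 immediate early genes, 9 rose and 4 fell, also when adjusted over the list alone (9 and 4; adjusted p = 0.036, and adjusted p = 0.098 with an estimated correlation). FOSL1 was at least 3.87-fold higher and the phosphatase gene DUSP5 rose 4.15-fold. Of 26 hypoxia and glycolysis genes, 10 rose and 5 fell, also when adjusted over the list alone (10 and 5; list adjusted p = 0.10), with ADM 6.33-fold and SLC2A1 2.66-fold higher.

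Outside these lists, the largest rises included the trypsin inhibitor SPINK1 (40.5-fold), GADD45B (28.8-fold), the cytokine signalling inhibitor SOCS2 (22.7-fold) and ASB5 (22.1-fold). DIRC3, NR2F1-AS1 and NMRAL2P were at least 19.4, 13.5 and 6.23-fold higher. Among the largest falls, the methyltransferase TMT1A, the GABA transporter SLC6A13, RASSF10, TMEM37, the protease ADAMTS9 and CLDN2, a claudin of leaky tubular epithelium, were 25.4, 18.6, 17.4, 13.2, 10.3 and 9.84-fold lower. BLNK, ENPP3, EPHA4 and IRX5 were at least 17.8, 10.3, 8.95 and 4.85-fold lower.

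Of the 11 lists past the threshold at 48 h, 5 also passed with an estimated correlation. Second probe sets gave no call for TMT1A (-0.17), PSMD12 (0.16) or HMGCS1 (-0.39), and the DDIT3 call ended without any 1 of 9 arrays, all but CdCl 12 h replicates 1 and 3 and control 12 h replicate 3 (adjusted p = 0.051 to 0.14).

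**Figure D3:**
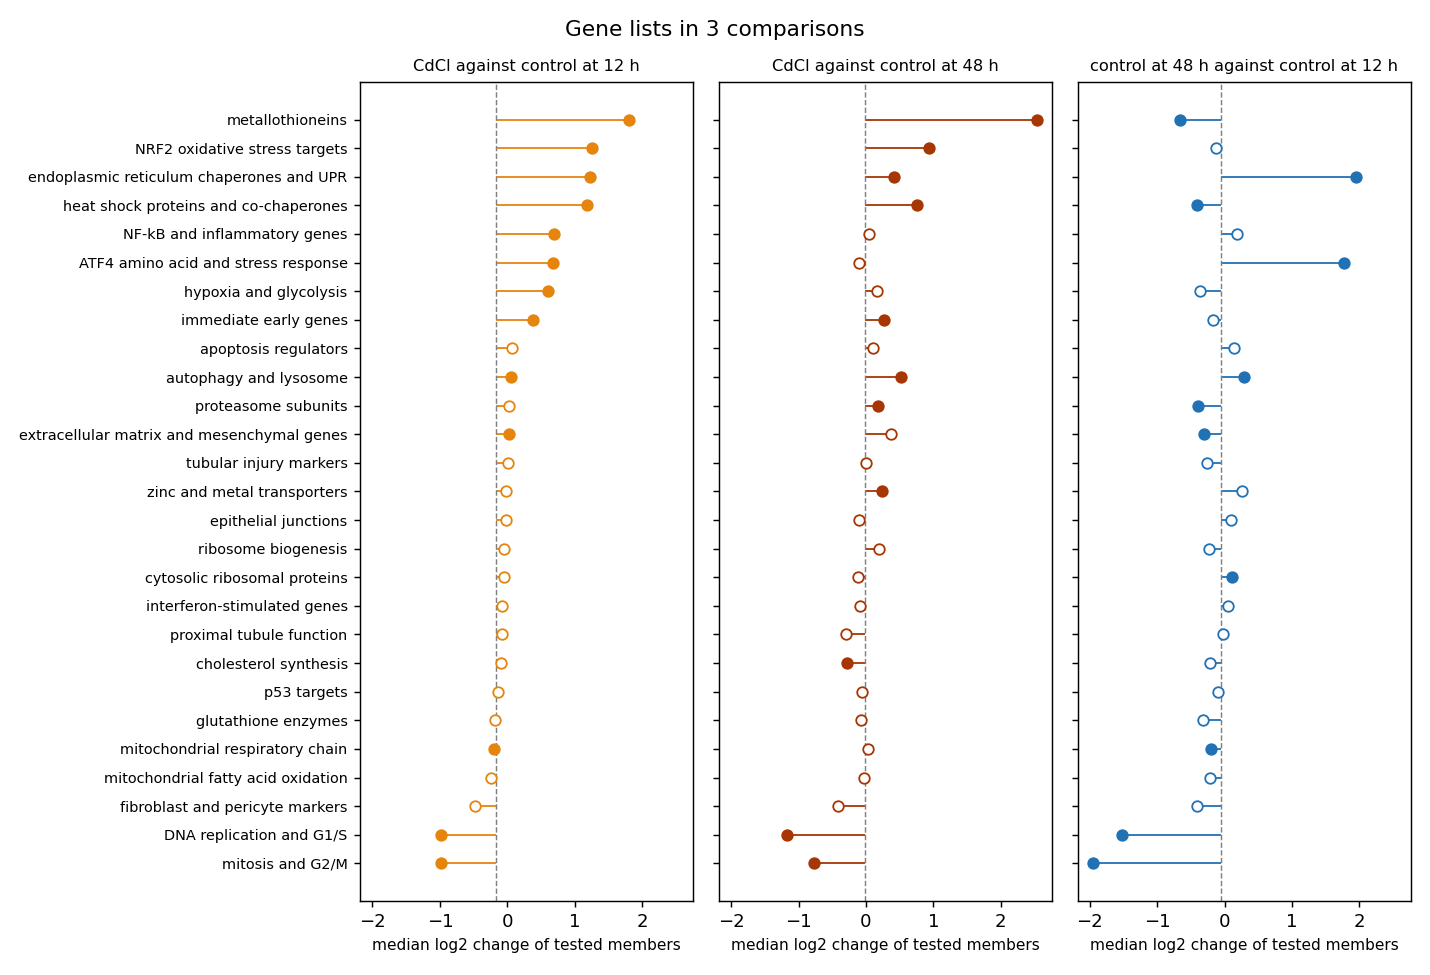
Median log2 change of the tested members (x) of 27 gene lists (y) with CdCl at 12 h, with CdCl at 48 h and in control cells over time, where filled points mark lists with a camera adjusted p under 0.05 and the dashed line marks the median of all tested genes. Metallothioneins stand highest with CdCl at both times, and the endoplasmic reticulum and ATF4 lists rise in control cells over time (1.95 and 1.77).

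The interaction asked whether the effect of CdCl differed between the times. Changes of endoplasmic reticulum, ATF4, heat shock, hypoxia and inflammatory genes were larger at 12 h. Metallothionein changes were larger at 48 h (adjusted p = 0.0016, and adjusted p = 0.14 with an estimated correlation). From 12 h to 48 h their median change was -0.66 in control cells and 0.06 in CdCl cells, where 0 rose and 0 fell, with MT2A and MT1X near the top of the scale. DDIT3 rose by 4.01 at 12 h and 0.20 at 48 h, a difference of -3.81 ± 0.11 (adjusted p = 4.2e-09), as its control level went from 7.48 to 12.73 while its CdCl level went from 11.50 to 12.93. The effect differed in 4282 of 10683 genes, more positive at 48 h in 2888 and more negative in 1394, with a median difference of 0.13, and list medians of the interaction are given relative to it. Among calls, 67.4% were more positive at 48 h as deposited and 48.9% after centring each array on its median.

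Of 30 ATF4 genes, 24 were more negative and 1 more positive at 48 h, also when adjusted over the list alone (24 and 1), with a median -0.95 from all genes (camera adjusted p = 1.3e-15). In the endoplasmic reticulum list 12 of 22 were more negative and 0 more positive, with 12 and 2 adjusted over the list alone (median -0.91 from all genes, adjusted p = 3.0e-08). In the heat shock list 16 of 25 were more negative and 0 more positive, also when adjusted over the list alone (16 and 0; median -0.49, adjusted p = 3.0e-08). In the hypoxia and glycolysis list 17 of 26 were more negative and 1 more positive, also when adjusted over the list alone (17 and 1; median -0.80, adjusted p = 2.3e-09). More negative and more positive members numbered 9 and 1 of 17 NF-kB genes, 10 and 1 adjusted over the list alone (median -0.67, adjusted p = 2.4e-05). They numbered 8 and 4 of 19 immediate early genes, 10 and 4 adjusted over the list alone (median -0.47, adjusted p = 0.0041), and 10 and 5 of 28 replication genes, 12 and 5 adjusted over the list alone (median -0.43, adjusted p = 0.0024). For 19 cholesterol genes they numbered 7 and 2, also when adjusted over the list alone (7 and 2; median -0.28, adjusted p = 0.0072). These 8 lists also passed with an estimated correlation. After centring each array on its median, 17 and 4 replication genes, 11 and 2 immediate early genes, 13 and 1 NF-kB genes and 15 and 0 endoplasmic reticulum genes were more negative and more positive.

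Metallothioneins were more positive at 48 h in 7 of 8 genes and more negative in 0, also when adjusted over the list alone (7 and 0; median 0.61 above all genes, adjusted p = 0.0016, and adjusted p = 0.14 with an estimated correlation). NRF2 targets were more negative in 12 and more positive in 5 of 29, also when adjusted over the list alone (12 and 5; adjusted p = 0.0022, and adjusted p = 0.069 with an estimated correlation), and proximal tubule genes in 7 and 2 of 14, 8 and 2 adjusted over the list alone (adjusted p = 2.7e-04, and adjusted p = 0.086 with an estimated correlation). The largest positive differences were in DIRC3 (3.61 ± 0.41), DLL1, a Notch ligand (3.23 ± 0.09), GADD45B (3.11 ± 0.15), SOCS2 (3.07 ± 0.47) and the neuronal immediate early gene ARC (3.01 ± 0.53). The largest negative ones were in ATF3 (-5.01 ± 0.24), ZFAND2A (-4.13 ± 0.21), SLC7A11 (-3.86 ± 0.15), DDIT3 and HSPA6 (-3.73 ± 0.16). From 12 h to 48 h in CdCl cells, ATF3 changed by 0.28 (limma adjusted p = 0.18) and SLC7A11 by 0.24 (limma adjusted p = 0.064), while both rose in control cells. SLC7A11 control arrays lay at 6.32 to 6.56 at 12 h and 10.45 to 10.57 at 48 h. ZFAND2A and HSPA6 changed by -1.21 and -3.755 in CdCl cells, with HSPA6 under 4 in control cells at each time. DLL1, ARC and DIRC3 lay under 4 in control cells at both times and DLL1 and ARC also in CdCl cells at 12 h, so the sizes of their differences depend on signals near background.

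Control cells at 48 h against 12 h show what time in culture changed without CdCl. Endoplasmic reticulum and ATF4 genes rose, and replication and mitosis genes fell. ATF3 rose 39.1-fold and DDIT3 38.0-fold (5.25 ± 0.08, adjusted p = 2.9e-12), and TXNIP, a thioredoxin inhibitor whose transcription follows glucose, fell from 9.60 ± 0.15 to 3.70 ± 0.52 (SD, n = 3). Of the genes tested, 2502 were higher and 3574 lower at 48 h, 436 and 711 by at least 2-fold, with a median change of -0.06.

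All 22 endoplasmic reticulum genes rose, 22 adjusted over the list alone (median 1.95, camera adjusted p = 9.5e-19), and 28 of 30 ATF4 genes rose and 1 fell, also when adjusted over the list alone (28 and 1; median 1.77, adjusted p = 3.7e-20). Mitosis genes fell in 28 of 28, also when adjusted over the list alone (28; median -1.96, adjusted p = 8.1e-17), and replication genes in 26 of 28, 27 adjusted over the list alone (median -1.52, adjusted p = 4.4e-13). Autophagy genes rose in 14 and fell in 3 of 24, also when adjusted over the list alone (14 and 3; adjusted p = 0.0041). These 5 of 11 lists also passed with an estimated correlation. Metallothioneins fell in 7 of 8 (adjusted p = 0.0068, and adjusted p = 0.26 with an estimated correlation), heat shock genes in 14 of 25 (0.019, and adjusted p = 0.37 with an estimated correlation), proteasome subunits in 23 of 28 (3.0e-05, and adjusted p = 0.26 with an estimated correlation), extracellular matrix genes in 14 of 21 (0.0010, and adjusted p = 0.10 with an estimated correlation) and respiratory chain genes in 18 of 31 (0.011, and adjusted p = 0.37 with an estimated correlation). Cytosolic ribosomal protein genes rose in 5 of 26 (adjusted p = 0.019, and adjusted p = 0.33 with an estimated correlation). Adjusted over the list alone these counts were 7, 14, 23, 14, 18 and 5, and after centring 7, 13, 17, 10, 13 and 15.

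Other large rises in control cells were in the activin subunit gene INHBE (38.7-fold), the stress regulator NUPR1 (29.0-fold) and BEX2 (19.7-fold). Apart from TXNIP, the largest falls were in MMP1, the sodium channel SCN3A and the calcium pump regulator SLN, which were at least 10.0, 6.26 and 6.05-fold lower, and in the kinetochore gene SPC25 (8.81-fold lower). Harvest time and any handling that differed between the 12 h and 48 h arrays cannot be separated in this comparison, and 49.3% of its calls were lower after centring each array on its median, against 58.8% as deposited.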

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

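The tests of a shared scaling offset and of a ceiling of the signal were chosen only after the result was seen. So were the value given for separate handling and the comparison between the CdCl groups at 48 h and 12 h. The effect of CdCl differed between 48 h and 12 h, by a test of the difference itself, in 4282 genes. List medians of the difference, 48 h minus 12 h, not relative to the 0.13 of all genes, were -0.82 for ATF4 genes, -0.79 for endoplasmic reticulum genes, -0.67 for hypoxia and glycolysis, -0.55 for NF-kB and inflammatory genes, -0.46 for proximal tubule function, -0.37 for heat shock, -0.34 for immediate early genes, -0.30 for replication, -0.21 for NRF2 targets, -0.155 for cholesterol synthesis (-0.0946 without CdCl 12 h replicate 2) and 0.74 for metallothioneins.

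Of the named genes that differed, 35 had a more positive change at 48 h. Metallothionein and metal transport genes among them were MT1M (1.68), MT2A (0.85), MT1G (0.82), MT1X (0.65), MT1F (0.42), SLC30A2 (0.53) and SLC30A1 (0.26), with MT2A and MT1X near the top of the scale in CdCl cells. Growth and DNA repair genes that fell at 12 h were BLM (1.90), ESPL1 (1.84), DDB2 (1.69), E2F2 (1.19) and CENPF (0.55), beside OLFML2A (2.43), FAM111A-DT (1.33) and H1-10 (1.32). Genes of the mesenchymal, injury, junction and immediate early lists were LCN2 (2.32), SNAI1 (1.54), SNAI2 (1.52), MMP1 (1.08), CD44 (0.91), CLDN4 (0.64), FOSL1 (1.00) and DUSP5 (0.74). The others were DIRC3 (3.61), DLL1 (3.23), GADD45B (3.11), SOCS2 (3.07), ARC (3.01), NMRAL2P (1.47), CTSD (1.44), HRK (1.23), OAS3 (1.22), SPINK1 (1.06), NQO1 (0.55) and PSMC4 (0.34).

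A more negative change at 48 h was seen in 65 named genes. Genes of the endoplasmic reticulum, ATF4, heat shock and NRF2 lists were ATF3 (-5.01), DDIT3 (-3.81), SLC7A11 (-3.86), HSPA6 (-3.73), AKR1B10 (-2.78), DNAJB9 (-2.17), DNAJC3 (-2.01), NUPR1 (-2.39), HSPA5 (-1.47 on a probe set near the top of the scale, -2.71 on its second), PHGDH (-1.45), SDF2L1 (-1.34), BAG3 (-1.27), DNAJB1 (-1.18), DNAJB11 (-0.86), PPP1R15A (-0.76) and HSPH1 (-0.39). Genes of the inflammatory, immediate early, hypoxia, p53 and apoptosis lists were IL11 (-2.90), HK2 (-2.06), TNFAIP3 (-1.80), PMAIP1 (-1.43), SESN1 (-1.20), SLC2A1 (-1.03), GADD45A (-0.99), GDF15 (-0.95), IER5 (-0.76), ADM (-0.57) and IL6 (-0.54). Genes of tubule function, junctions, injury and metal transport were SLC4A4 (-3.09), CLDN2 (-2.80), VCAM1 (-2.75), CDH16 (-1.97), CDH6 (-1.69), HAVCR1 (-1.62), GJA1 (-1.54), ABCC2 (-1.22), SLC40A1 (-1.10), CCN2 (-0.63) and SLC39A14 (-0.54).

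Genes of growth, lipid metabolism and autophagy with a more negative change at 48 h were PDK4 (-2.16), CDT1 (-1.56), STARD4 (-1.17), HMGCS1 (-1.17), ACSL1 (-1.05), MCM5 (-1.03), INSIG1 (-0.98), HSD17B7 (-0.94), MAP1LC3B (-0.62), NUSAP1 (-0.52) and KIF20A (-0.43). The others were ZFAND2A (-4.13), ENPP3 (-3.55), BLNK (-3.50), TMT1A (-3.09), ADAMTS9 (-3.02), SLC6A13 (-3.01), RASSF10 (-2.96), EPHA4 (-2.86), TMEM37 (-2.80), ANKRD1 (-2.58), CLIP4 (-2.55), DLX2 (-2.51), INHBE (-1.96), IRX5 (-2.19), BEX2 (-2.17) and IFI44L (-1.49). Where a gene lay under 4 in a group, the size of its difference rests on signals near background. The direction of FOSL1 turned to -0.14 with a floor at 4, and on second probe sets those of MT1G, NQO1 and MAP1LC3B turned to -0.22, -0.23 and 0.11, none of these past the threshold.

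Leaving out 1 array ended the calls of 4 of these genes. The ABCC2 call ended without control 12 h replicate 1 or 2, CdCl 12 h replicate 1 or 2 or control 48 h replicate 2 or 3 (adjusted p = 0.051 to 0.062), and its difference was -0.80 without CdCl 48 h replicate 1. The FOSL1 call ended without control 12 h replicate 2 or 3, CdCl 12 h replicate 2, control 48 h replicate 2 or 3 or CdCl 48 h replicate 3 (adjusted p = 0.051 to 0.061). The SLC30A1 call ended without control 12 h replicate 2, CdCl 12 h replicate 1, control 48 h replicate 1 or CdCl 48 h replicate 1 or 3 (adjusted p = 0.054 to 0.076), and the SPINK1 call without control 12 h replicate 2 or 3 (adjusted p = 0.050 to 0.054).

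The 4282 genes of the interaction were set against 100 splits, drawn from the 200 possible, that exchange times between arrays within a treatment. Counts as large came from 2 of the 100, the real one included. The other, with 7350 genes, exchanged all time labels of 1 treatment. It thus measures the sum of the time changes, a structure of the samples, and the next highest gave 3527. A split that mixes times within a group puts the time change into the spread, which lowers its count. The splits therefore cannot exclude chance for this count. At 12 h, at 48 h and in control cells over time, 6 arrays make 10 splits, of which 1, the real one, gave as many genes (6029, 5830 and 6076), with 0 as the highest of the other splits. Splits of 6 arrays are too few for a share under 0.05.

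Genes lower with CdCl at 12 h outnumbered higher ones, 4246 against 1783, and poly-A spike-ins, outside the gene comparisons, were higher in the CdCl 12 h arrays by 0.468 on the log2 scale. The tables argue against 1 scaling offset shared by all probe sets of an array, since genes at levels of 12 to 14 had a median change of -0.0602 (95% bootstrap interval -0.09 to -0.02), above the -0.16 of all tested genes. A level-dependent bias left by the normalization stays open, since 58.2% of calls were lower after quantile normalization, under the bound set beforehand for such a bias. That step would also remove a true shift, a reservation added after the value was seen, so bias and a true fall of many transcripts cannot be told apart here. A fall of many transcripts with CdCl, which could also raise the share of the spike-ins, is a hypothesis that was not tested.

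Endoplasmic reticulum and ATF4 genes responded less to CdCl at 48 h than at 12 h, and rose in control cells over time, by medians of 1.95 and 1.77, more than between the CdCl groups, 1.11 and 1.09. A ceiling of the signal is argued against for the 32 of 52 members under 12 in all groups. Their median difference was -0.77 (95% bootstrap interval -1.11 to -0.33), a reading that used both the bound written for the median and the interval. Members that reached 12 in a group, DDIT3, DNAJB9 and HSPA5 among them, were not in this test, and a ceiling stays open for them. Separate handling of the 12 h and 48 h arrays that adds the same shift to CdCl and control arrays cancels from the interaction by construction. The median time change of control minus CdCl was 0.82 (95% bootstrap interval over genes 0.54 to 1.07). This is the interaction with its sign turned, so it restates the pattern and is no separate test of handling. Handling that differed by group stays open. A candidate explanation is low glucose in the medium of the 48 h cultures, which may raise these genes in control cells. TXNIP changed by -5.72 from 12 h to 48 h in CdCl cells too (limma adjusted p = 4.3e-09), so its fall does not set control cells apart. The explanation was tested on only 1 gene, named for it beforehand. ARRDC4, which like TXNIP is transcribed less when glucose is low, was at least 1.81-fold lower in control cells at 48 h (4.86 to 3.41, under 4 on all 3 arrays). The fitted change was -1.45, and -0.86 with limma adjusted p = 6.0e-04 when floored at 4, a weak signal from 1 gene. Its means in CdCl cells were 4.42 at 12 h and 3.65 at 48 h, so it was lower there too. The test therefore cannot tell why endoplasmic reticulum and ATF4 genes rose more in control cells, and the explanation stays open.

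Of 2711 tested probe sets that carry no gene name or several, which the gene comparisons do not use, 412 were higher and 670 lower with CdCl at 12 h, and 503 higher and 607 lower at 48 h.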

How the results depend on the processing

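No alternative was chosen only after the result was seen. Of named genes 302 results were tested, 271 past the threshold, and of gene lists 108, 46 past it. Direction or side of the threshold changed in 8 gene and 6 list results after centring each array on its median. It changed in 5 and 4 after quantile normalization, in 7 and 0 with a floor at 4 and in 5 and 5 with no filter. It changed in 7 and 2 with array weights, in 4 and 3 with eBayes trend and robust and in 4 and 2 with a replicate block. With every probe set it changed in 1 and 3, and with an adjusted p under 0.01 in 13 and 8. A 2-fold minimum changed 47 gene results, and the list tests do not use it. Fewer results could be had with the filter at 6 (2 of 290 gene and 3 of 108 list results changed), the mean of all probe sets (7 of 294 and 7 of 108), only the groups compared (1 of 172 and 1 of 81) and second probe sets (19 of 270, of which 11 lost the call, 4 gained it and 4 reversed, and 8 of 104). An estimated correlation ended 17 list calls, and with fry 37 lists gained a call and 1 reversed. With the group mean of each gene subtracted, same-number arrays correlated at -0.336 to 0.158 in 18 pairs, so no pairing by number was seen. Values under 4 are near background, which limits fold changes of weak genes to bounds.

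Centring on the array median left 2830 genes lower at 12 h and 1907 more positive in the interaction, by its construction removing the shared shift. Second probe sets gave 2714 and 1910, with 8439 genes tested. Every probe set on its own gave 3801 higher at 12 h, 4523 higher and 4930 lower at 48 h, 2910 more negative in the interaction, and 4728 higher and 5395 lower in control cells over time, with 19005 tested. An adjusted p under 0.01 left 1773 more positive and 852 more negative in the interaction. A 2-fold minimum left 473 and 433 at 12 h, 515 and 540 at 48 h, 419 and 371 in the interaction and 436 and 711 over time. Lists past the threshold, 13 at 12 h and 11 in each other comparison, numbered 5 at 48 h and 5 over time with an estimated correlation, and 20, 23, 18 and 23 with fry, which does not compare a list with other genes.

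Results that reversed were the interaction of FOSL1, -0.14 with a floor at 4, and, on second probe sets, HK2 at 12 h (-0.52) and the interactions of MAP1LC3B (0.11), MT1G (-0.22) and NQO1 (-0.23). Why probe sets of a gene differ was not tested, and in FOSL1 the floor raises the low control values by construction. With fry the cytosolic ribosomal protein list at 12 h (median -0.0466) was called down, while camera, against a median of -0.16 for all genes, gave up and no call.

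Leaving out each array in turn gave 1601 to 1853 genes higher and 3741 to 4414 lower at 12 h, 2493 to 2812 and 2658 to 2971 at 48 h, 2477 to 2861 and 1174 to 1421 in the interaction, and 2207 to 2586 and 3180 to 3676 over time. The transporter list call at 48 h ended without control 48 h replicate 1 or 2 or CdCl 48 h replicate 3 (adjusted p = 0.051 to 0.065), and the list passed at 12 h without control 12 h replicate 2 (adjusted p = 0.041). The cholesterol call at 48 h ended without control 48 h replicate 3 or CdCl 48 h replicate 3 (adjusted p = 0.053 to 0.060). ISG20 at 12 h gave 0.67 without control 12 h replicate 1.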

Other observations

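No test here was chosen only after the result was seen. Apoptosis regulators moved both ways with CdCl. At 12 h 8 of 23 rose and 6 fell, and at 48 h 10 rose and 6 fell, the same counts as when adjusted over the list alone, with 11 higher and 5 lower at 12 h after centring (camera adjusted p = 0.10 and 0.32). PMAIP1, the BH3-only gene NOXA, rose by 2.46 ± 0.07 and 1.04 ± 0.07 (SE), and HRK, another BH3-only gene, was at least 2.00-fold higher at 12 h and rose by 2.92 ± 0.15 at 48 h. Epithelial junction genes rose in 3 and fell in 6 of 23 at 12 h (3 and 3 adjusted over the list alone, 7 and 2 after centring each array on its median) and in 7 and 5 at 48 h (7 and 5), with adjusted p = 0.34 and 0.94. The claudin CLDN4 rose by 0.87 ± 0.11 and 1.52 ± 0.11, and the connexin GJA1 rose by 0.98 ± 0.08 at 12 h and fell at 48 h, with a change of -0.56 ± 0.08. Interferon-stimulated genes rose in 2 and fell in 4 of 17 at 12 h and in 5 and 7 at 48 h, also when adjusted over the list alone (adjusted p = 0.63 and 0.60), with 4 higher and 2 lower at 12 h after centring. OAS3 changed by -1.27 ± 0.16 at 12 h, ISG20 was at least 1.41-fold higher at 12 h and 4.42-fold at 48 h, and IFI44L changed by -1.94 ± 0.21 at 48 h.

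Fatty acid oxidation genes fell in 10 and rose in 0 of 21 at 12 h, but in 2 and 2 after centring each array on its median, and at 48 h 6 fell and 3 rose (adjusted p = 0.25 and 0.36). PDK4, a kinase that restrains pyruvate oxidation, changed by -2.48 ± 0.12 and the acyl-CoA synthetase ACSL1 by -1.14 ± 0.12 at 48 h. Glutathione enzymes rose in 7 and fell in 11 of 21 at 12 h, and 6 and 6 at 48 h (adjusted p = 0.25 and 0.79), and ribosome biogenesis genes rose in 4 and fell in 7 of 26 at 12 h and in 12 and 4 at 48 h (adjusted p = 0.39 and 0.16). Adjusted over the list alone these counts were the same, while after centring the 12 h counts were 7 higher and 6 lower for glutathione enzymes and 6 and 2 for ribosome biogenesis. Cytosolic ribosomal protein genes fell in 2 of 26 at 12 h and 4 at 48 h, 0 and 0 adjusted over the list alone (adjusted p = 0.63 and 0.12), and after centring 4 were higher and 0 lower at 12 h. At 12 h the proteasome list had 4 genes higher and 2 lower of 28 (adjusted p = 0.094), 11 and 1 after centring, and at 48 h the respiratory chain list had 4 higher and 12 lower of 31 (adjusted p = 0.60).

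Markers of other renal cell types were mostly under the filter. The filter also removed many genes of proximal tubule function: of 36 in that list, 31 had a probe set and 14 were tested. Of fibroblast and pericyte markers 5 were tested, of which 3 fell and 0 rose at 12 h and 3 fell and 1 rose at 48 h, the same when adjusted over the list alone (adjusted p = 0.39 and 0.20). Of distal tubule and collecting duct markers 3 were tested, too few for a list test, and 1 fell at 12 h and 2 at 48 h. Of endothelial and of leukocyte markers 0 were tested.

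A hypothesis fixed beforehand was that zinc finger genes may fall with CdCl more than other genes of their level. The 341 tested genes whose symbols start with ZNF had a median change of -0.0443 at 12 h, with 62 higher and 79 lower, against a median of -0.20 (95% range -0.25 to -0.14) in 10000 random sets matched on level. The list lay above the matched sets, so the test argues against the hypothesis, a reading of values above that range which was settled after they were seen, and camera gave an upward direction that did not pass (adjusted p = 0.080).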
